A study of Elopichthys bambusa with 12 samples.

How the data were processed

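RNA sequencing of liver was analysed in 12 samples of yellowcheek carp, 3 in each of 4 groups: fish fed for 8 days, fasted for 8 days, fed for 28 days and fasted for 28 days. Per the labels' protocols, total RNA with an integrity number of 7 or more went into stranded mRNA libraries, which were read as pairs of 125 or 150 nucleotides on one or another of the named Illumina instruments. Which library was read on which instrument is not given in the sources used here. Per the submitters' processing notes, Trimmomatic and Bowtie2 were among the tools, without versions. The assembler, the program that estimated abundance and the annotation are not given in the sources used here. The identifiers have the form that the Trinity assembler writes, each with a further last number from 1 to 4.

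The authors deposited 2 tables of 42353 features and 12 libraries. The first holds estimated counts per feature, as deposited by the authors, which are not whole. This would follow if reads that match several features were shared between them, which was not tested. Values of near-identical features may therefore be uncertain. The second holds FPKM values made by the authors, that is, fragments per kilobase of feature relative to the size of the library. The columns were matched to samples through the group codes in the series' design text and the replicate number. Dividing counts by FPKM gave the length of each feature, and 100% of these lengths were whole within 0.02 nucleotides. The library totals behind the FPKM values were 95.8% to 105.1% of the column totals of the count table. Total estimated counts ran from 16785827 to 19901335 per library.

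The design fixed before the data were examined assumed counts. The deposited estimated counts were rounded to whole numbers for the count tests. Features with too few counts were left out with edgeR's filterByExpr by group, which kept 32212 features, left out 10141 and kept 99.7% to 99.8% of the counts. All 12 libraries were fitted together as 4 group means with edgeR 4.0.16 (R 4.3.3), with TMM scaling (factors 0.83 to 1.22), robust dispersion and quasi-likelihood estimates, and the quasi-likelihood F test. The common dispersion was 0.29. P-values were adjusted over all tested features by the Benjamini-Hochberg method, and a feature passed at an adjusted p under 0.05. The comparisons were fasted against fed at 8 and at 28 days, the difference between these, 28 against 8 days in fasted and in fed fish, and the mean of the fasting effects. Standard errors of log2 fold changes were taken from the fold change and its F statistic, are approximate, and are not given where a group had no count. CPM values (counts relative to library size) are scaled by the TMM factors, and group values are means ± SD over 3 libraries. Abundance classes use the highest group mean among the groups compared. Shares of counts are percentages of a library's total.

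The features named were set by a rule fixed before the data were examined: for each fasting comparison, the 2 risen and 2 fallen features with the largest absolute log2 fold change among those that passed the test, reached 10 CPM in the higher group and had no overlap between the 6 libraries. This rule was met by 4037 features at 8 days and 1883 at 28 days. Where a group had no count, the fold is a lower bound against 3 counts per library. The files do not pair the identifiers with gene names, so the gene lists and cell type markers fixed beforehand were not run.

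Libraries were related by principal components and Pearson correlation of log2 CPM with a prior count of 2. Numbers of detected features and shares of the most abundant ones were compared by exact two-sided permutation tests, which cannot give a p below 0.1 with 3 against 3 libraries. The 12 pairs of libraries within a group were checked for duplication by a chi-square test over features with at least 20 counts, which gave 12.2 to 65.2 per feature. Overlaps were set beside those of independent lists, in which every feature is taken as equally likely to pass whatever its abundance. For comparisons with shared libraries they were also set beside 5 simulations of unchanged groups.

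The test was checked on simulated counts drawn from the means, dispersions and library sizes of the real features, with 200 of 32212 features, all at 1 CPM or more, changed by 2 to 16-fold. Of the features changed by 4-fold it found 50% for the 8-day, 38% for the 28-day and 48% for the fasted 28 against 8 day comparison, with 1, 3 and 1 false calls.

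The alternatives were other scalings (RLE, upper quartile, library size alone), other filters, thresholds of an absolute log2 fold change of 1 or an adjusted p of 0.01, non-robust estimation, the replicate number as a block, only the libraries compared, DESeq2 1.42.0, limma 3.58.1 on log2 FPKM with pseudocounts of 1 and 0.1, and leaving out each library in turn. Added after the data were seen were the other fed group as control, removal of each library's trend with feature length, and setting aside 3 fasted libraries. Other splits of the libraries were also tested, with 100 of the 200 relabellings within days, among them the real labels, those with 1 day turned round and 98 drawn at random. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.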

Results

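Liver gene expression was profiled by RNA sequencing in yellowcheek carp (Elopichthys bambusa), a predatory freshwater cyprinid, that were deprived of food for 8 or 28 days or were kept on a commercial diet for the same time. Each of the 4 groups (fed 8 days, fasted 8 days, fed 28 days and fasted 28 days) was represented by 3 liver libraries. The libraries held between 16785827 and 19901335 estimated counts, over 42353 assembled transcript features of 301 to 11930 nucleotides with a median of 598 nucleotides. The features carried identifiers of a de novo assembly that the files do not pair with gene names, so the results are given for groups of features and for a few features by identifier. No 2 libraries of a group held the same counts within sampling noise, and all 12 were treated as separate samples. The labels do not say whether the 3 libraries of a group came from single fish or from pools, and the p-values measure the spread between these libraries.

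The first question was how the 12 livers related to each other. The fed 8-day libraries stood apart from the other 9. On the first principal component, which held 33% of the variance, they scored 186.3 to 195.5 and the other 9 libraries -87.9 to -37.9. The second component (18.7%) set the fed 28-day libraries, at -156.9 to -111.6, apart from the 6 fasted libraries, at 26 to 98.2, while the fasted groups of both days overlapped. On the third component (8.8%) the fasted libraries parted without regard to the day. Replicate 2 of the fasted 8-day group and replicates 2 and 3 of the fasted 28-day group lay between -77.3 and -54.7, and the other fasted libraries between 62.2 and 112.1. Across features, which are not independent replicates, the correlation of log2 CPM (counts relative to the scaled size of the library) averaged 0.741 ± 0.015 (SD over 27 pairs) between a fed 8-day library and one of the other 9. It averaged 0.837 ± 0.037 among those 9 (36 pairs) and 0.872 ± 0.023 between fasted 8-day and fasted 28-day libraries (9 pairs). Within the fed 8-day group it was 0.904 ± 0.009 (3 pairs).

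**Figure D1:**
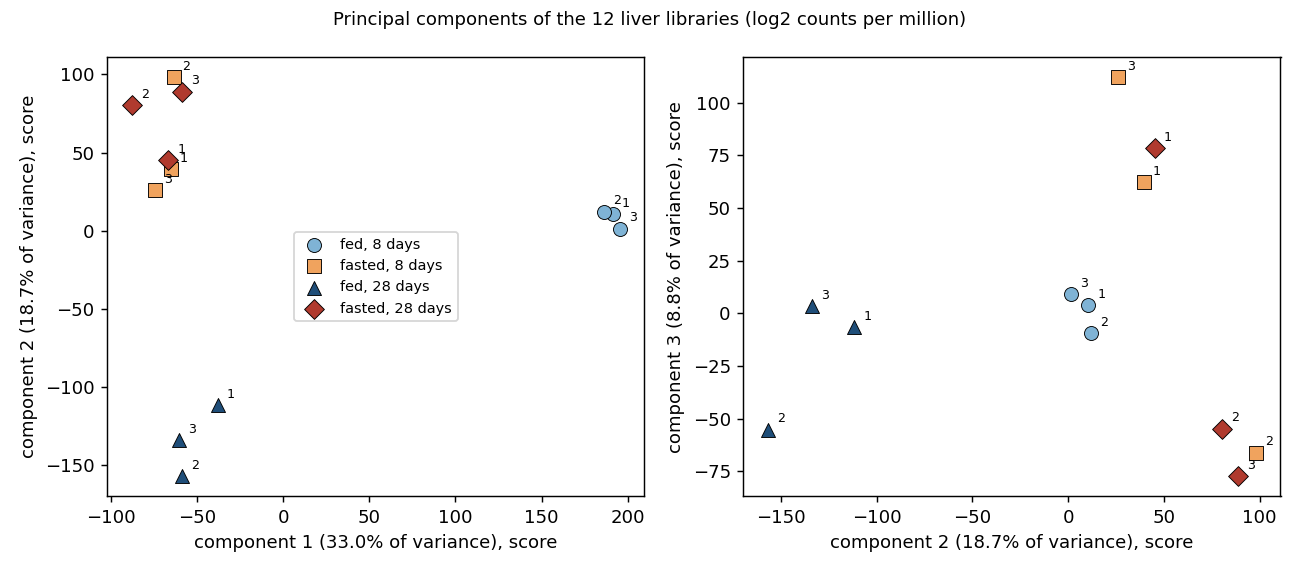
Scores of the 12 libraries on the first 3 principal components of log2 CPM, with symbols for the 4 groups and the replicate number beside each symbol. The 3 fed 8-day libraries lie at 186.3 to 195.5 on component 1 and the fed 28-day libraries at -156.9 to -111.6 on component 2, while the fasted libraries of both days overlap.

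More features were detected in fasted than in fed livers, in libraries not equalised for depth. At least 1 estimated count was recorded for 38020 ± 1007 features in fasted and 36731 ± 635 in fed fish at 8 days (mean ± SD, n = 3 each), and for 38754 ± 900 and 36834 ± 46 at 28 days. Each fasted library lay above each fed library of its day. The exact two-sided permutation test gave p = 0.1 on both days, the smallest value that 3 against 3 libraries allow. At a minimum of 10 counts the difference was 1451 features at 8 days (exact permutation p = 0.5), where the groups overlapped, and 3607 at 28 days (p = 0.1). The size of the 8-day differences depended on single libraries. Without replicate 2 of the fasted 8-day group, one of those set apart on the third component, they were 716 features at 1 count and 245 at 10 counts. At 1 count, leaving out each library in turn gave 716 to 1662.5, and the groups never overlapped. At 10 counts the difference was 926 without replicate 3 of the fed and 2179 without replicate 3 of the fasted 8-day group. At 28 days fasted replicates 2 and 3, also set apart on that component, had 30129 and 27420 features at 10 counts, against 25879 in replicate 1 and 24147 to 24257 in fed fish. The 100 most abundant features took 56.7% ± 2.1 of the counts in fasted and 52.6% ± 0.3 in fed fish at 8 days (exact permutation p = 0.1). At 28 days they took 55.6% ± 1.1 and 56.6% ± 1.0 (exact permutation p = 0.3). For the 10 and the 1000 most abundant, fasted minus fed was 2.47 and 1.93 percentage points at 8 days (exact permutation p = 0.2 and 0.4). It was -1.5 and -2.4 at 28 days (exact permutation p = 0.1 for each). At this depth a feature with no count in a library can be at up to 3 counts, which is about 0.16 CPM at 8 days, and this covers counting error only.

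The comparison of fasted with fed fish at 8 days asked what a short fast changed. Of 32212 features tested, 4278 were higher and 3885 lower in fasted than in fed livers, 25.3% of those tested, with a median absolute log2 fold change of 1.74. Among them, 1090 rose and 726 fell by 8-fold or more. The features that rose held 16.5% ± 0.83 of all counts in fed and 38.8% ± 2.31 in fasted fish (n = 3 each), and those that fell held 25.6% ± 2.8 and 6.15% ± 0.33. Of the 170 most abundant features, those over 1000 CPM in at least 1 of the 2 groups, 57 rose and 31 fell, whereas of the 5811 features between 10 and 100 CPM 1459 rose and 1972 fell.

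The largest changes at 8 days, by the rule set before the data were examined, were in features seen in only one of the 2 groups. The feature TRINITY_DN19001_c0_g1_i1_1 (353 nucleotides) had no count in any fed 8-day library and 56.8 ± 49.9 CPM in fasted fish, at least 356-fold higher against a floor of 3 counts per library (edgeR adjusted p = 0.000142, higher in 3 of 3 libraries). TRINITY_DN15102_c0_g2_i1_2 (708 nucleotides) went from no count to 22.1 ± 10 CPM, at least 138-fold higher (edgeR adjusted p = 0.000458). Both were also present in fed fish at 28 days, at 68.8 ± 22.6 and 21.4 ± 7.31 CPM, and did not differ between fasted and fed fish then (edgeR adjusted p = 0.93 and 0.638). TRINITY_DN23877_c0_g1_i1_3 (674 nucleotides) and TRINITY_DN10025_c0_g1_i2_4 (923 nucleotides) were at 46.6 ± 1.97 and 39.6 ± 4.55 CPM in fed 8-day fish and had no count in the fasted fish, at least 295-fold and 251-fold lower (edgeR adjusted p = 4.23e-05 and 0.000178). In fed 28-day fish the same pair was at 1 ± 0.788 and 0.573 ± 0.496 CPM. The identifiers of the risen pair end in 1 and 2, and those of the fallen pair in 3 and 4. Among features with at least 30 counts and over 60% of their summed CPM in 1 library, number 3 prevailed for fed 8-day replicate 2. Number 4 prevailed for fed 8-day replicates 1 and 3, and numbers 1 and 2 for no fed 8-day library. Assembly from different libraries may therefore contribute to these presences and absences, which was not tested for these features.

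The 3 and 3 libraries did not overlap for 43.8% of the features tested at 8 days, against 10% by chance, and for 8006 of the 8163 that passed the test. The number of changed features rested on the control group: set against the fed 28-day libraries instead, a choice made after the data were seen, the fasted 8-day fish differed in 2530 features, 1482 of them among the 8163. The balance of directions was not settled: 52.4% of the features were higher in fasted fish, 50.4% to 56.3% with other scalings of the libraries, 46.6% with a fit of only the libraries compared, 46.5% with the trend with feature length removed, and 40.6% of 8376 with limma on log2(FPKM + 1), which changes the test and the scale at once.

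The comparison at 28 days asked the same of a long fast. Here 1333 features were higher and 1864 lower in fasted than in fed livers, 9.9% of the 32212 tested, with a median absolute log2 fold change of 1.43. By 8-fold or more, 237 rose and 262 fell. Among abundant features more fell than rose: of the 176 over 1000 CPM, 12 rose and 45 fell, and of the 859 between 100 and 1000 CPM, 84 rose and 272 fell, while the rest did not pass the test. The features that fell held 27.7% ± 1.48 of all counts in fed and 14.5% ± 0.34 in fasted fish (n = 3 each), and those that rose held 3.52% ± 0.08 and 10.3% ± 1.19.

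The features with the largest rise at 28 days, TRINITY_DN16768_c0_g1_i2_3 (1536 nucleotides) and TRINITY_DN25998_c0_g1_i1_4 (520 nucleotides), were nearly silent in all 6 fed livers. The former was at 0.152 ± 0.0426 CPM in fed and 130 ± 53 in fasted 28-day fish, 853 times as much (log2 fold change 9.68 ± 0.97 SE, edgeR adjusted p = 0.00022). Its fed value rests on 7 counts and lies under the 0.195 CPM of 3 counts per library, so this ratio is uncertain. The latter was at 0.914 ± 0.313 and 369 ± 172, 403 times as much (8.65 ± 0.82, adjusted p = 0.000153). Both had also risen at 8 days, to 98.7 ± 69.6 and 248 ± 205 CPM (log2 fold changes 9.19 ± 0.94 and 8.00 ± 0.79, edgeR adjusted p = 5.61e-05 and 4.4e-05). TRINITY_DN14406_c0_g1_i8_4, a feature of 4359 nucleotides, was at 7950 ± 356 CPM in fed and 13.7 ± 1.32 in fasted fish at 28 days, and at 7390 ± 476 and 10.8 ± 1.65 at 8 days. It was 581 and 683 times as high in fed as in fasted fish, and its log2 fold changes of -9.18 ± 0.19 at 28 days and -9.41 ± 0.20 at 8 days had edgeR adjusted p-values of 1.37e-09 and 1.16e-09. Its identifier ends in 4, like that of the risen TRINITY_DN25998_c0_g1_i1_4. Number 4 prevailed for fed 8-day replicates 1 and 3 and fed 28-day replicate 1. Whether assembly or near-identical features contribute to this change was not tested. TRINITY_DN7732_c0_g1_i1_4 (321 nucleotides) was at 10.9 ± 2.48 CPM in fed 28-day fish with no count in the fasted fish, at least 74.3-fold lower (edgeR adjusted p = 0.0374), and passed the test in none of the 6 fits that left out 1 of the 28-day libraries (adjusted p = 0.0658 to 0.103; over all alternatives 0.00295 to 0.235).

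The libraries did not overlap for 31.6% of the features at 28 days, against 10% by chance. The number of changed features fell from 3197 to 1830 without replicate 2 and to 1905 without replicate 3 of the fed 28-day group, and to 1704 and 1738 without replicates 2 and 3 of the fasted 28-day group; DESeq2 gave 5468. Of the alternatives chosen after the data were seen, the fed 8-day libraries as control gave 8809, and setting aside the 3 fasted libraries that lay together on the third component gave 1080. The predominance of falling features held with RLE and upper-quartile scaling (39.4% and 41.1% higher, against 41.7%) and turned in other settings: with library size alone 69.1% of 3624 features were higher in fasted fish, 36 of the most abundant rose and 26 fell, and the median log2 fold change of all features moved from 0.1 to 0.45, while limma on log2(FPKM + 1) gave 63.3% higher.

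**Figure D2:**
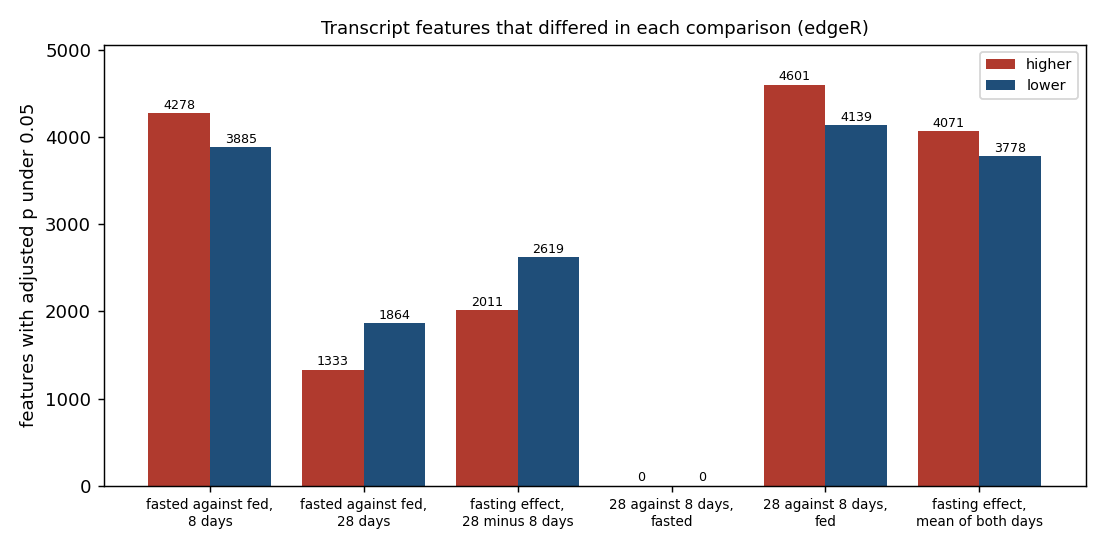
Number of transcript features with an edgeR adjusted p under 0.05 in each of the 6 comparisons, of 32212 tested, drawn as bars for features higher and lower in the first-named group (for the third pair, features with a larger or a smaller log2 fold change of fasting at 28 than at 8 days). The bars stand at 4278 and 3885 for fasting at 8 days, 1333 and 1864 at 28 days, and 0 for 28 against 8 days in fasted fish; the balance of higher and lower bars turned under some of the alternatives in each of the other 5 comparisons.

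**Figure D3:**
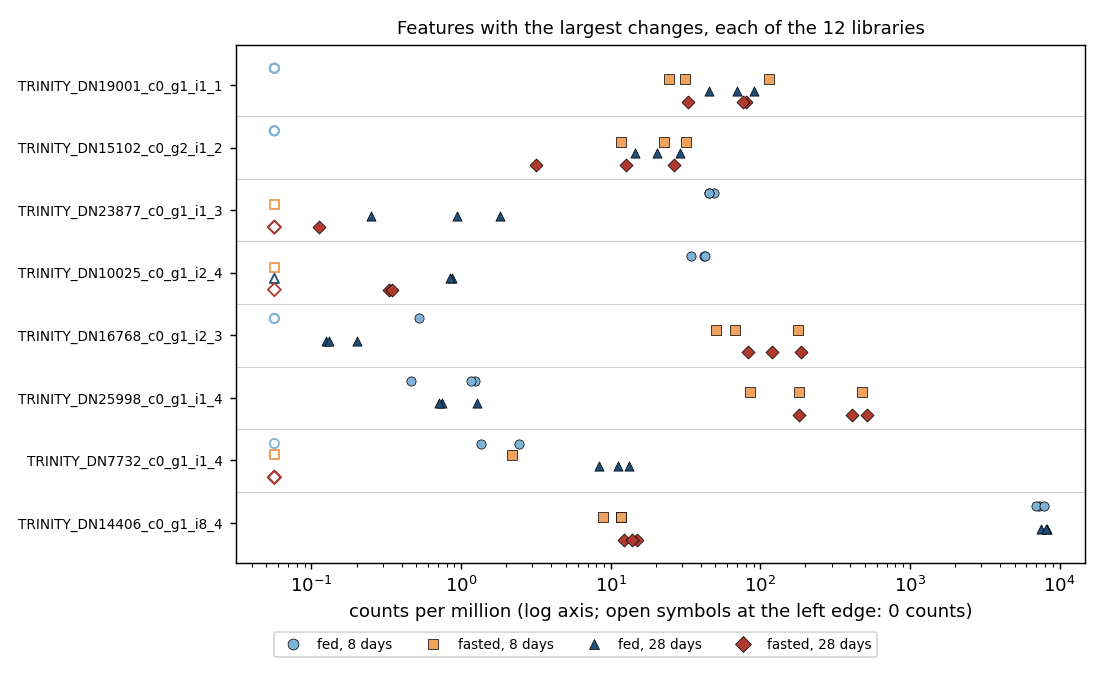
CPM, on a log axis, of the 8 features named for the fasting comparisons in each of the 12 libraries, with a symbol and colour for each group; open symbols at the left edge are libraries with no count. The upper 4 features separate the fed 8-day libraries from the others, and TRINITY_DN14406_c0_g1_i8_4 in the bottom row is at 6980 to 8220 in the 6 fed libraries and 8.91 to 14.9 in the 6 fasted libraries.

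A set of features responded to fasting in the same direction on both days. It held 540 features that rose and 830 that fell at 8 and at 28 days, against 177 and 224.8 that independent lists of these sizes would share. Independent lists take every feature as equally likely to pass, so they understate what power alone would share, in either direction. Between 10 and 100 CPM 25.1% rose and 33.9% fell at 8 days, and 9.7% and 19% at 28 days. Under 10 CPM these shares were 9.8% and 6.3% at 8 days, and 2.8% and 2.2% at 28 days. Of the 540, 503 were higher in all 6 fasted than in all 6 fed libraries, and of the 830, 787 were lower. Both sets were chosen for passing the test in these same libraries. This separation, the fold changes and the shares of counts given next follow in large part from that choice. The median log2 fold change of the risen features was 1.66 at 8 and 1.36 at 28 days, and that of the fallen ones -1.55 and -1.39. The risen set held 2.79% ± 0.06 of all counts in fed and 7.96% ± 1.89 in fasted fish at 8 days, and 3.07% ± 0.04 and 8.88% ± 1.09 at 28 days (n = 3 each). The fallen set held 12.7% ± 0.83 and 3.17% ± 0.09 at 8 days, and 10% ± 1.04 and 3.1% ± 0.13 at 28 days. At least 8-fold changes on both days were seen in 35 risen and 111 fallen features. A further 376 features, against 408.3 for independent lists with the same limit, passed the test on both days in opposite directions. That number was 216 and 228 without replicate 2 or 3 of the fed 28-day group, 225 and 205 without replicate 2 or 3 of the fasted 28-day group, 703 with DESeq2 and 151 without the 3 fasted libraries that lay together on the third component. Across all features, which are not independent replicates, the log2 fold changes of the 2 days correlated with r = 0.17. The shared set of 1370 shrank to 883 and 880 without replicate 2 or 3 of the fed 28-day group and to 831 and 875 without replicate 2 or 3 of the fasted 28-day group. It was 564 without the 3 fasted libraries of the third component, DESeq2 gave 2094, and with library size alone 819 features rose and 580 fell on both days.

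The next comparison tested whether the response to fasting differed between the 2 durations. The fold change of fasted over fed fish differed in 4630 features, 14.4% of those tested by edgeR. Of these, 2011 had a larger and 2619 a smaller log2 fold change at 28 than at 8 days, with a median absolute difference of 2.18. The same contrast is the change from 8 to 28 days in fasted fish minus that in fed fish. By itself the former passed in 0 features and the latter in 8740. The 4630 features therefore cannot be ascribed to the longer fast rather than to the fed groups. Among the 197 features over 1000 CPM in any group 3 had a larger and 60 a smaller value at 28 days (5 and 42 with library size alone), and the rest did not pass. Of the 9614 features that changed on either day, 4226 differed between the days. Of the 1370 that changed the same way on both, 232 differed, 195 with the larger change at 8 and 37 at 28 days. Among the named features, TRINITY_DN19001_c0_g1_i1_1, TRINITY_DN15102_c0_g2_i1_2 and TRINITY_DN10025_c0_g1_i2_4 differed between days (edgeR adjusted p = 0.000753, 0.00176 and 0.006). The responses of TRINITY_DN14406_c0_g1_i8_4, TRINITY_DN16768_c0_g1_i2_3 and TRINITY_DN25998_c0_g1_i1_4 differed by 0.23 ± 0.19, 0.49 ± 1.54 and 0.65 ± 0.94 on the log2 scale (± SE, edgeR adjusted p = 0.493, 0.888 and 0.721). Those of TRINITY_DN23877_c0_g1_i1_3 and TRINITY_DN7732_c0_g1_i1_4, each without counts in 1 group, had large fitted differences of 8.08 and -9.83 but did not pass (edgeR adjusted p = 0.0941 and 0.0775). The share of features with the larger value at 28 days was 43.4%, and it became 63.9% with library size alone and 71.7% with limma on log2(FPKM + 1).

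Fish fasted for 28 days were compared with those fasted for 8 days. No feature passed edgeR's test, 894 had an unadjusted p under 0.05, and the libraries did not overlap for 6.9% of features, below the 10% that chance gives. DESeq2 called 34 features and limma called 2 on log2(FPKM + 0.1) and 0 on log2(FPKM + 1). In counts simulated at this depth and spread, the same test found 48% of features changed by 4-fold and 74% of those changed by 16-fold, but 0% of those changed by 2-fold, so small differences were not detectable here. Without replicate 2 of the fasted 28-day group 1 feature passed. The fasted libraries also parted on the third component without regard to the day. This widens the spread within both groups and makes overlap between them more likely. The split of the 6 libraries along that division passed 2062 features by edgeR. No fit allowed for that division in this comparison, so the absence of calls does not show the 2 groups to be alike.

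Fed fish, in contrast, differed widely between the 2 sampling days. Of 32212 features 4601 were higher and 4139 lower in fed fish at 28 than at 8 days, with a median absolute log2 fold change of 1.87. Of the 179 features over 1000 CPM, 66 were higher and 6 lower at 28 days (55 and 20 with library size alone), and the rest did not pass. Many of these features also passed for fasting at 8 days, which shares the fed 8-day libraries: 2999 were higher and 2482 lower in both, where independent lists would share 611 and 499.2. Unchanged groups simulated with the same shared libraries pass almost no feature in either comparison, so their 0 shared features set no scale for this overlap. The covariance of the log2 fold changes was 2.94 against 0.46 in the simulation, and their correlation across features 0.72 against 0.5. The 3 shared libraries were too few to divide between the comparisons. The features that rose at 8 days of fasting held 29.5% ± 1.33 of the counts in fed 28-day fish, between the 16.5% ± 0.83 of fed 8-day and the 40.2% ± 2.2 of fasted 28-day fish. These features were chosen for being lower in the same fed 8-day libraries than in fasted ones. Selection alone therefore tends to place other groups above the fed 8-day share, and the value is no separate evidence of a difference. With library size alone 38.6% of the features were higher at 28 days, and with limma on log2(FPKM + 1) 33.2%, against 52.6%.

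Averaged over both days, 4071 features were higher and 3778 lower in fasted than in fed fish, with a median absolute log2 fold change of 1.19. A feature can pass here through 1 day alone, and only 540 and 830 passed in the same direction on both days. The 8-day part rests on the fed 8-day libraries, which stood apart. Of the 197 features over 1000 CPM in any group 53 rose and 52 fell. The share that rose was 51.9%, but 63.4% with library size alone, 49.5% with RLE scaling, 45.5% with the trend with feature length removed, and 45.4% to 52.5% with 1 library left out.

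Changed features were longer and more abundant than the rest. Such features collect more counts and give the test more power, so this need not be a property of the response to fasting. Features that differed between the fed groups also had a longer median, 1239.5 against 648 nucleotides. The median length was 1302 nucleotides for the 8163 features that changed at 8 days and 646 for the 24049 that did not, and 1469 and 711 at 28 days. Their median abundance was 6.54 CPM against 1.39 at 8 days, and 9.85 against 1.67 at 28 days. The median log2 fold change varied with length: it was 0.37 at 8 and 0.31 at 28 days among features of 301 to 350 nucleotides, -0.02 on both days among those of 1254 to 1668 nucleotides, and 0.29 and 0.01 among those of 2357 to 11930 nucleotides, against 0.16 and 0.1 over all features.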

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

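The tests of assembly from other libraries and of separate handling were chosen after the results they bear on were seen, and the removal of the length trend was added after the data were seen; the relabelling of libraries was planned before, and the relabelling that turns 1 day round was added after its result was known. The response to fasting differed between 28 and 8 days in 4630 features by edgeR's test of the difference. Relabelling fasted and fed within each day tests for no fasting effect on either day, not for an equal effect on both, and so does not decide whether this number arose by chance: of 100 relabellings, from 200 and the real labels included, 2 gave as many features, and the highest other, with the labels of 1 day turned round, gave 7849. In 376 features the response passed the test on both days in opposite directions, where independent lists would share 408.3. All 376 also passed the test of the difference. That nearly follows from passing on both days in opposite directions, so it is no further evidence. Leaving out 1 library gave 205 to 446 such features, with 205, 216, 225 and 228 without replicate 3 of the fasted, 2 of the fed, 2 of the fasted and 3 of the fed 28-day group, DESeq2 gave 703, and 151 were left without the 3 fasted libraries that lay together on the third principal component.

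Among the named features, the fitted log2 fold change of fasting at 28 minus that at 8 days was -13.17 for TRINITY_DN19001_c0_g1_i1_1, -12.28 for TRINITY_DN15102_c0_g2_i1_2 and 11.28 for TRINITY_DN10025_c0_g1_i2_4. The edgeR adjusted p-values were 0.000753, 0.00176 and 0.006. These fitted values depend on the prior count and have no usable standard error. The first 2 features had no count in fed 8-day fish and the last had none in fasted 8-day fish.

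These differences go with the fed 8-day libraries, which stood apart from both fasted groups and from the fed 28-day group. A trend of the libraries with feature length is argued against as the whole cause, since 8706 features still differed between the fed groups with that trend removed, against 8740. An assembly built in part from libraries other than the fed 8-day ones may contribute and stays open: of the features that differed between the fed groups, 18.4% (704 of 3833) with identifiers ending in 1 or 2, 62.2% ending in 3 and 79.6% ending in 4 were lower in fed 28-day fish, against 47.4% of all, and a feature assembled from other libraries can also be higher in fed 8-day fish. Separate handling, sequencing or stock of the fed 8-day fish may also account for the pattern: 25 features were at 1 CPM or more in each fed 8-day library with no count in the other 9, against at most 1 for another group. This cannot be told apart from a biological difference of these fish, because all 3 libraries belong to 1 group and the labels assign no library to a batch. The labels name different instruments and read lengths but do not say which library was read on which. The sampling day and age of the fed fish also stay open, untested.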

How the results depend on the processing

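The control group, length trend, set of 3 fasted libraries and, for detected features, leaving out each library were alternatives chosen after the data were seen. The gene lists and their alternatives were not run, since identifiers are not paired with names, and a fit of only the libraries compared does not exist for the difference and the mean, which use all 12. At an adjusted p under 0.01 the features numbered 4704 (fasting at 8 days), 1239 (28 days), 1960 (difference), 4885 (fed fish, 28 against 8 days) and 4428 (mean), and 549 changed the same way on both days; fewer pass by construction. With an absolute log2 fold change of at least 1, the mean gave 4829 and both days shared 888. DESeq2 gave 5468 at 28 days, 2094 shared by both days and 34 for 28 against 8 days in fasted fish, where limma on log2(FPKM + 0.1) gave 2; the cause was not tested. With the other fed group as control, 8 days gave 2530 and 28 days 8809, and the log2 fold change of TRINITY_DN19001_c0_g1_i1_1 became -0.28 (adjusted p = 0.843, against 0.000142; in the other alternatives 2.37e-19 to 0.00463), by the construction of that control. Likewise TRINITY_DN15102_c0_g2_i1_2 went from 11.68 to 0.04 (adjusted p = 0.983; otherwise 1.28e-14 to 0.00196) and TRINITY_DN10025_c0_g1_i2_4 from -12.53 to -6.42 (0.0742; otherwise 4.88e-15 to 0.00104). Without the 3 fasted libraries that lay together on the third component, 28 days gave 1080, 8 days 6930 and both days shared 564, with 1 and 2 fasted libraries left; the lone 28-day sample was assumed to vary like the other groups. With a filter of 1 CPM the mean correlation of fed 8-day with other libraries was 0.713, and at 10 counts the excess of detected features in fasted fish at 28 days was 3606.67.

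Leaving out each library in turn gave 6221 to 6968 features at 8 days, 1704 to 3281 at 28 days, 3258 to 4520 for the difference, 0 to 1 for fasted fish, 6620 to 7651 for fed fish, 6370 to 7617 for the mean and 831 to 1459 shared by both days. The excess of features detected in fasted fish was 716 to 1662.5 at 8 days, lowest without replicate 2 of the fasted group, and 1418.5 to 2288.5 at 28 days. At 28 days the number moved by over 1.5 times without replicate 2 (1830) or 3 (1905) of the fed and replicate 2 (1704) or 3 (1738) of the fasted 28-day group, as did the number shared by both days (883, 880, 831 and 875). All other settings left each of these numbers of changed or shared features within 1.5 times. The balance of directions was less stable: over all alternatives the share higher was 39.4% to 56.3% at 8 days, 31.9% to 69.1% at 28 days, 38.3% to 71.7% for the difference, 33.1% to 57.6% for fed fish and 45.4% to 63.4% for the mean.

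The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.16 to 0.14 over 18 pairs, 2 of them above 0.1, and 4 of 12 libraries correlated best with their own number. With the replicate number as a block the features numbered 7638 (8 days), 2882 (28 days), 4078 (difference), 0 (fasted), 8162 (fed) and 7346 (mean). Of 192 values of the 8 named features under alternatives, 179 kept direction and call, 12 lost the call without a change of sign, 10 of these for TRINITY_DN7732_c0_g1_i1_4 and 2 with the other fed group as control, and 1 reversed. Depth limits features near 3 counts per library, and with 3 libraries per group changes of 2-fold were mostly missed in simulated counts.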

Other observations

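The tests of the last number of the identifiers against libraries were chosen after the pattern was seen; the test within classes of length and abundance and the splits were set before. Features present in 1 group alone were few outside the fed 8-day fish. No feature was at 1 CPM or more in each fasted 8-day or each fasted 28-day library with no count in the other 9, and 1 was so in fed 28-day fish, against 25 in fed 8-day fish. A further 21 features were missing from the fed 8-day libraries alone. Between the fasted groups, 1 feature was present at 8 days alone and 4 at 28 days alone by the same rule.

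The sum of FPKM values was 714092 ± 23931 in fed 8-day fish (n = 3) and 598836 ± 22942, 598304 ± 22259 and 599557 ± 11520 in fasted 8-day, fed 28-day and fasted 28-day fish. The sums depend on how the counts spread over features of different length and on the library total behind the FPKM values, which was 96.63% ± 1.36 of the column total in fed and 102.2% ± 2.85 in fasted 8-day fish (exact permutation p = 0.1). At 8 days the sums of fed and fasted fish differed with an exact permutation p = 0.1, the smallest that 3 against 3 allow.

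The direction of the 8-day response went with the last number of the identifier. Of features ending in 4, 28.6% fell and 3.7% rose with fasting at 8 days, and of those ending in 1 and 2, 6.2% and 4.3% fell and 20.8% and 20.1% rose. Differences in length and abundance are argued against, since within 25 classes of both the excess of falling features among those ending in 4 was 22.7 percentage points, against 23.5 overall. A candidate explanation is that the number marks separate assemblies made from different libraries: of 332 features with over 60% of their summed CPM in 1 library and at least 30 counts, 95.5% carried the most common number of that library, against at most 55.7% in 1000 permutations. Number 4 was the most common for fed 8-day replicates 1 and 3 and fed 28-day replicate 1, so features found mainly in fed livers may be overrepresented among those ending in 4, and no biological explanation was tested. Of those ending in 3, 10.5% fell and 10.5% rose at 8 days. The pattern differed at 28 days: 9.7% of features ending in 4 fell and 2.7% rose, and 7.7% and 3.3% of those ending in 1. For number 2 these shares were 4.6% and 3.9%, and for number 3 they were 3.3% and 5.5%.

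For fasting at 8 days, 1 of the 10 splits of the 6 libraries gave as many as 8163, the real one, and the highest other gave 0. At 28 days it was 1 of 10, with 3197 and at most 2, and for fed fish at 28 against 8 days 1 of 10, with 8740 and at most 1. For fasted fish at 28 against 8 days all 10 splits gave at least the real 0, as any split must, so this count tests nothing. The highest gave 2062, with at most 2 in the rest. The 10 splits are too few for a share under 0.05. The split with 2062 put replicates 1 and 3 of the fasted 8-day group with replicate 1 of the fasted 28-day group, which is the division on the third principal component and points to a structure of the fasted samples other than the day; the labels name none. For the mean effect of fasting 1 of 100 relabellings within days gave as many as 7849, the real one. Such a number is thus unlikely if the fasted and fed labels carry no difference on either day. It does not tell fasting from another difference of the fed 8-day libraries. The highest other, with the labels of 1 day turned round, gave 4630, and the highest of the 98 drawn at random gave 2924, with all 8-day labels kept.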
